A study of Anguilla anguilla with 30 samples.

How the data were processed

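Total RNA of eel liver was extracted with TRIzol, and 50 ng per sample was labelled with Cy3, per the labels. Each of the 30 samples was hybridised alone to a custom eel array of 62976 features, of which 61657 are not controls. The submitters' processing notes and the file headers name Agilent Feature Extraction 10.7.3.1. The deposited scanner files give each spot's signal as an intensity, background-subtracted and detrended within the array and not normalised between arrays, per the file headers. The deposited value table holds log2 values, centred on the mean of the 6 day 0 arrays. What the authors did to reach it is not stated, and it lies closest to quantile-normalised log2 signal (correlation across probes per array from 0.926 to 0.992). It holds 42469 probes, and no column of per-sample values was left unused.

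Groups were taken from the labels: day 0, and upstream and downstream at day 3 and day 15, with 6 arrays each. The labels name the effluent as agent for the upstream arrays of day 3 and day 15 too, and they call the day 0 arrays control. The 30 arrays lie on 4 slides that each hold all 5 groups, in nearly the same order on every slide. Signal was well above background on 43.97% to 67.2% of spots per array, and the 75th percentile of log2 signal ran from 7.83 to 9.12. Between 2 and 55 outlier spots per array were left out, and at most 1 spot was saturated.

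Levels are the log2 processed signal minus the 75th percentile of the array. Spots with an identical sequence were averaged into 1 probe, which gave 43466 sequences, a choice made before any test. A probe was tested when it was well above background on at least 4 of the 6 arrays of at least 1 group. Group means were fitted to all 30 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with version 1.17.8 of the data.table package, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. There were 9 comparisons: the sites at each time, the interaction of site and time, and the days at each site. The fit was tested on simulated data with each probe's mean and within-group spread over all 30 arrays and independent noise. Changes were added to the downstream day 3 arrays and read in the day 3 site comparison. Variation shared between probes was left out, so recovery and false calls on the real arrays may differ. Of 50 changed probes at each size, 10%, 58%, 78% and 84% were recovered at log2 changes of 0.5, 1, 1.5 and 2, and 4 unchanged probes were called.

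The array names are cut short, so gene families rather than genes were read from many of them. Targets that share a probe sequence were joined into 1 transcript, represented by its brightest probe, and this joining was chosen after the counts of probes and a first table of named genes had been seen. Of 14245 transcripts on the array, 3075 had an informative name. None of 123 public accessions on the array was found in the RefSeq table of gene names, so no genome position was used. A fold is written "at least" where a probe was well above background on 0 arrays of the dimmer group. It then sets the brighter group's mean against the mean, over the dim arrays, of the higher of the probe's own signal and the lowest signal among probes well above background.

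Named genes were chosen by a rule fixed before the data were examined: the 10 largest rises and falls past the threshold, up to 4 passing members with the largest change in each list, the 5 lowest p-values where fewer than 5 passed, and a fixed set of exposure markers in the site comparisons. In the comparisons of days the text names only part of these genes, mostly those that kept their call when any 1 array was left out. Over the 9 comparisons in the order of the counts plot, 1 of 5, 3 of 7, 0 of 1, 10 of 22, 87 of 127, 54 of 84, 78 of 112, 94 of 117 and 78 of 121 genes of the rule kept their call in every such refit.

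Gene lists numbered 36 before the data were examined, and 12 were added after the array names were seen and before any test. Members were matched to the shortened names by hand, which departs from a match on full symbols. Of these lists 40 were tested, 6 held fewer than 3 transcripts and the others had no named member. The tests were limma's camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists of a comparison. Camera with the preset correlation called 83 lists over the 9 comparisons, and none of these calls held with an estimated correlation.

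Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile and median scaling, no filter and a filter on all 30 arrays, slide as a block, slide with position, only the groups compared, trended and robust moderation, array weights, the deposited values, a minimum log2 change of 1 and each array left out in turn. Alternatives added later were identical sequences kept apart, targets not joined, the 4 arrays with under 50% of spots well above background left out, a mucin score as covariate, and for the lists no hand-matched names, only the earlier lists and median scaling. For each comparison 100 splits of its arrays were drawn, the real one included. Figures were drawn with matplotlib 3.10.9.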

Results

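Liver RNA of immature European eels (Anguilla anguilla) was measured on 30 one-colour microarrays that carry eel transcript sequences. The eels were caged upstream or downstream of a point that receives paper-industry effluent. There were 5 groups of 6 samples: day 0, which the labels call control and upstream, and both cage sites at day 3 and at day 15. The labels do not state that each sample was a single eel, so p-values measure the spread between these samples. They do not measure a spread between sites, since the groups hold only an upstream and a downstream location. Signal well above the local background was found on 56.8% of the spots of an array on average, from 43.97% to 67.2%. The group means were 56.2% ± 6.44 (SD, n = 6) at day 0, 52.1% ± 5.87 upstream and 57.2% ± 3.28 downstream at day 3, and 57.7% ± 6.72 upstream and 60.7% ± 5.28 downstream at day 15. The number of arrays limits the precision of every difference given here. Levels are log2 signal relative to the 75th percentile of the array, and each change is a log2 difference ± the standard error of the limma fit between groups of 6 arrays. Of 26405 probes tested, which stand for 9481 transcripts, 2233 transcripts had an informative name. The array's library transcripts are written as E with their number, and because the array shortens their names, a name is read as a gene family. No genome position is paired with these transcripts in the files.

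**Figure D1:**
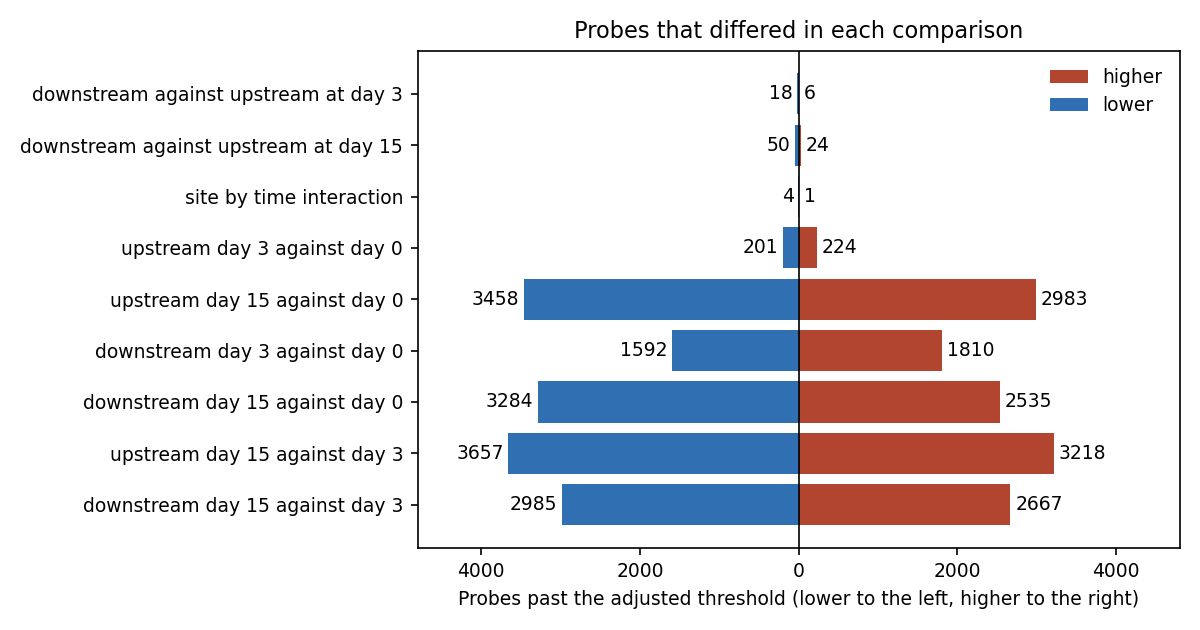
Number of probes past an adjusted p of 0.05 in limma in each comparison, with lower probes drawn to the left and higher probes to the right. The site comparisons hold 24 and 74 probes, and the comparisons of day 15 with day 3 hold 6875 and 5652.

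Downstream against upstream at day 3 addressed what differed below the effluent after 3 days of caging. A Pi-class glutathione S-transferase, an enzyme that couples glutathione to reactive compounds, was 2.51-fold higher downstream (log2 1.33 ± 0.25, adjusted p = 0.0228). Its level was 3.43 ± 0.38 downstream and 2.10 ± 0.47 upstream (SD, n = 6). A high mobility group transcript (E-02037), of a family of chromatin proteins, was 1.94-fold lower downstream (log2 -0.95 ± 0.13, adjusted p = 0.000394). Also lower were a transcript whose name begins with peptidoglycan (E-03371, log2 -1.52 ± 0.28, adjusted p = 0.0192) and E-01727 (log2 -0.65 ± 0.13, adjusted p = 0.0449), whose name begins with gamma-glutamyl. A transcript of the same shortened name, E-01726, was well above background on 5 upstream arrays and on 0 downstream arrays and was at least 2.75-fold lower downstream (adjusted p = 0.0449), although not on slide 4 (0.45). For each of these 5 transcripts all 6 downstream arrays lay on the same side of the upstream mean, and 4 of the 5 had the same direction on each of the 4 slides. Calls were made on these same arrays, so agreement of arrays or slides, here and in later comparisons, is not separate support.

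The marker genes fixed for this comparison did not pass, apart from the transferase. CYP1A, the cytochrome P450 induced through the aryl hydrocarbon receptor, differed by log2 0.89 ± 0.26 (adjusted p = 0.236), with 6 of 6 downstream arrays above the upstream mean. The other differences were 0.46 ± 0.37 for CYP1A9, 0.17 ± 0.41 for metallothionein (E-02654), -0.16 ± 0.35 for metallothionein 1, 0.40 ± 0.26 for a UDP-glucuronosyltransferase and -0.31 ± 0.42 for estradiol receptor alpha, with adjusted p from 0.669 to 0.943. The tested CYP3A transcripts, named as cytochrome P450 3a, differed by 0.24 ± 0.37 (E-01183) and 0.27 ± 0.44 (E-01182). Heme oxygenase 1 differed by -0.76 ± 0.73 with signal well above background on 1 downstream and 2 upstream arrays. The adjusted p of these transcripts lay between 0.799 and 0.902. Vitellogenin, the egg yolk precursor used as a marker of estrogens, 70 kDa heat shock transcripts and a further transcript named CYP3A were on the array but too dim to test. Their signal was well above background on at most 4 of 30 arrays.

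Phase II conjugation enzymes were shifted upward at day 3 as a group. Of 25 transcripts, 1 rose and 24 did not pass, and 5 passed when adjusted over the list alone. The median log2 difference was 0.36 (adjusted p = 2e-07, and adjusted p = 0.206 with an estimated correlation). The 13 glucocorticoid and stress transcripts held none that passed in limma, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05. Their median was 0.47 (adjusted p = 0.00621, and adjusted p = 0.567 with an estimated correlation). The 41 proteasome transcripts lay lower as a group, with a median of -0.19 (adjusted p = 0.000186, and adjusted p = 0.722 with an estimated correlation). None of them passed, with 0 adjusted over the list alone and 4 at an unadjusted p under 0.05. Lists of mitochondrial ribosomal proteins, of the translocon and glycosylation and of tRNA synthetases, all added after the array's names were seen, were lower with medians of -0.18, -0.23 and -0.32. Their adjusted p was 0.00169, 0.00246 and 0.0253, against adjusted p = 0.807, 0.722 and 0.567 with an estimated correlation. None of their transcripts passed, and 3, 3 and 0 had an unadjusted p under 0.05. Among the cell-type lists no shift passed, and the lowest adjusted p was 0.582. Of 40 lists fry called 1 at day 3, against 6 by camera with the preset correlation.

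At day 3, limma called 24 of 26405 probes between the sites, 6 higher and 18 lower downstream, with 2526 at an unadjusted p under 0.05. With slide as a block 44 probes passed, all 24 among them, and on each of the 4 slides at least 95.8% of the 24 had the same direction. The count was 4 when only these 12 arrays were fitted and 8 with slide and array position in the fit. Of the 5 named transcripts only E-02037 kept its call in both fits (adjusted p = 0.0456 and 0.0327), and the others had adjusted p from 0.0672 to 0.21 and from 0.284 to 0.644. Array weights gave 90 probes and the filter on all 30 arrays 45, and the balance was 13 higher and 16 lower with median scaling and 12 and 15 with normexp. Without single arrays it ran from 11 to 27, with 12 without upstream replicate 9, 14 without upstream replicate 12, 11 without downstream replicate 15 or 18 and 12 without downstream replicate 17. E-02037 passed in each of the 12 refits, E-01726 only in the refit without upstream replicate 12 (log2 -3.60, against -2.85 on all arrays), and E-01727 only without downstream replicate 16, with adjusted p up to 0.119 and 0.111. The transferase lost its call without upstream replicate 9 (0.0922) or 12 (0.0768) or downstream replicate 13 (0.0541), 15 (0.0567), 17 (0.0858) or 18 (0.0762), and E-03371 without upstream replicate 9 (0.0714) or 12 (0.059) or downstream replicate 15 (0.0567) or 17 (0.0775).

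Downstream against upstream at day 15 asked the same question after the longer stay. A transcript named as a coenzyme Q10 homolog (E-00930) was 3.94-fold higher downstream (log2 1.98 ± 0.36, adjusted p = 0.0102). Keratin 8 (E-02354), an intermediate filament protein of simple epithelia, was 2.42-fold higher (log2 1.27 ± 0.28, adjusted p = 0.0411). Of 5 transcripts that were lower downstream, the clearest was a zinc finger transcript of the CCHC type (E-05268, log2 -0.87 ± 0.11, adjusted p = 0.000289). A pair of them, E-01727 (log2 -0.80 ± 0.13, adjusted p = 0.00597) and the high mobility group transcript E-02037 (log2 -0.60 ± 0.13, adjusted p = 0.0411), were those also lower at day 3. A further high mobility group transcript (E-02041, log2 -0.68 ± 0.14, adjusted p = 0.02) and a cellular nucleic acid-binding transcript (E-00747, log2 -0.49 ± 0.10, adjusted p = 0.0172) were lower as well. For all 7 the 6 downstream arrays lay on the same side of the upstream mean, and the direction was the same on each of the 4 slides. The same arrays had selected these transcripts, so this is not separate support.

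Among the markers at day 15, CYP1A differed by log2 0.25 ± 0.26 (adjusted p = 0.715) and the Pi-class transferase by log2 0.31 ± 0.25 (adjusted p = 0.619). The differences were -0.06 ± 0.37 for CYP1A9, 0.25 ± 0.41 for metallothionein (E-02654), -0.08 ± 0.35 for metallothionein 1, 0.21 ± 0.73 for heme oxygenase 1 and 0.17 ± 0.26 for the UDP-glucuronosyltransferase. They were 1.18 ± 0.37 and 0.34 ± 0.44 for the CYP3A transcripts E-01183 and E-01182 and -0.22 ± 0.42 for estradiol receptor alpha, and the adjusted p of these 8 lay between 0.156 and 0.962.

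Stress and conjugation genes lay higher downstream at day 15 as groups in camera with the preset correlation, although no transcript of these lists passed on its own. That test called 11 of 40 lists here, while fry called 2. The glucocorticoid and stress list had a median of 0.61 (adjusted p = 0.00445, and adjusted p = 0.383 with an estimated correlation). Of its 13 transcripts 6 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone. The unfolded protein response, phase II conjugation and DNA damage and p53 lists had medians of 0.56, 0.38 and 0.53. They had adjusted p of 0.00576, 0.00576 and 0.0137, against adjusted p = 0.383, 0.383 and 0.0937 with an estimated correlation. In these lists 3 of 6, 5 of 25 and 4 of 10 transcripts had an unadjusted p under 0.05, and 2, 3 and 3 passed adjusted over the list alone. Antioxidant, cell cycle and cholesterol synthesis genes were also higher as groups, with medians of 0.09, 0.41 and 0.52. Their adjusted p was 0.0416, 0.0439 and 0.0457, against adjusted p = 0.383 for each with an estimated correlation, and 1, 0 and 2 transcripts passed adjusted over the list alone, with 4, 2 and 2 at an unadjusted p under 0.05. Oxidative phosphorylation (median -0.13) and ribosomal proteins (median -0.17) were lower as groups, at adjusted p of 0.00576 and 0.00913, against adjusted p = 0.805 and 0.887 with an estimated correlation. None of their 96 and 84 transcripts passed, also when adjusted over the list alone, and 11 and 4 had an unadjusted p under 0.05.

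Cell-type markers differed at day 15 beside these groups. The bile duct epithelium list lay higher downstream, with 1 of 9 transcripts, keratin 8, past the threshold, also when adjusted over the list alone. As a protein of simple epithelia, keratin 8 does not mark bile ducts alone. The list's median was 0.58 (adjusted p = 0.00939, and adjusted p = 0.0937 with an estimated correlation). Markers of fibroblasts and stellate cells lay higher too, with a median of 0.52 (adjusted p = 0.0117, and adjusted p = 0.383 with an estimated correlation). Of these 8 none passed, 1 passed adjusted over the list alone and 4 had an unadjusted p under 0.05. Skeletal muscle and erythrocyte medians were 0.51 and 0.46, at adjusted p of 0.105 and 0.147. A score of mucin transcripts, which differed widely between arrays of every group, was 2.10 ± 3.15 (SD, n = 6) downstream and -0.83 ± 3.31 upstream.

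In limma 74 probes passed at day 15, 24 higher and 50 lower downstream, with 3430 at an unadjusted p under 0.05. With slide as a block 111 passed, 71 of the 74 among them, and per slide at least 95.9% of the 74 had the same direction. The count was 0 when only these 12 arrays were fitted (3062 at an unadjusted p under 0.05), 9 with slide and position, 17 without the 4 arrays with the least signal over background and 41 with the mucin score as a covariate. It was 138 with median scaling (21 higher and 117 lower), 139 with quantile scaling or the deposited values, and 95 with normexp (21 and 74). None of the 7 named transcripts kept its call in the fit of 12 arrays (adjusted p from 0.0852 to 0.202), and with slide and position only E-05268 did (0.00678). Without single arrays it ran from 42 to 97, with 44 without upstream replicate 19 and 42 without upstream replicate 21 or downstream replicate 29. Keratin 8 kept its call only without upstream replicate 23 or downstream replicate 30 and E-02037 only without upstream replicate 21 or 22 or downstream replicate 25 or 30, with adjusted p up to 0.12 and 0.103 in the other refits. E-02041 lost its call without upstream replicate 19 (0.0589) or 21 (0.0599) or downstream replicate 30 (0.0525), and E-00747 without upstream replicate 22 (0.0509).

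Whether the site difference changed between day 3 and day 15 was tested by the interaction of site and time. Of named transcripts only the cellular nucleic acid-binding E-00747 passed, with a site difference lower at day 15 than at day 3 by a log2 value of -0.75 ± 0.14 (adjusted p = 0.0469). The next lowest p-values belonged to an integrator complex transcript (E-02222, log2 0.72 ± 0.14, adjusted p = 0.0763), keratin 8 (log2 1.98 ± 0.39, adjusted p = 0.0916), CD83 (E-00719, log2 -2.36 ± 0.60, adjusted p = 0.238) and a transcript named as an epsilon subunit (E-01456, log2 0.97 ± 0.25, adjusted p = 0.238). Values were also taken for 3 transcripts chosen after their site differences were seen: -1.02 ± 0.36 for the Pi-class transferase (adjusted p = 0.394), -0.65 ± 0.37 for CYP1A (adjusted p = 0.566) and 0.35 ± 0.19 for E-02037 (adjusted p = 0.534). For these 3 a site difference at one time was thus not shown to differ from that at the other.

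As groups, the proteasome, bile duct epithelium and cholesterol synthesis had a higher site difference at day 15 than at day 3, with medians of 0.25, 0.46 and 0.75. They had adjusted p of 0.000416, 0.0171 and 0.0284, against adjusted p = 0.529, 0.214 and 0.315 with an estimated correlation. The lists of translocon and glycosylation (median 0.24) and mitochondrial ribosomal proteins (median 0.20), both added after the array's names were seen, were higher as well. They had adjusted p of 0.000912 and 0.0497, against adjusted p = 0.488 and 0.82 with an estimated correlation. Ribosomal proteins had a lower site difference (median -0.23, adjusted p = 0.00641, and adjusted p = 0.853 with an estimated correlation). In the interaction fry called 3 of 40 lists. No member of the 6 lists passed in limma, while 2 bile duct and 1 cholesterol synthesis transcripts did when adjusted over the list alone. An unadjusted p under 0.05 was found for 5 proteasome, 5 ribosomal, 2 bile duct, 1 cholesterol synthesis, 5 translocon and 2 mitochondrial ribosomal transcripts. The interaction held 5 probes, 1 higher and 4 lower, with 2587 at an unadjusted p under 0.05. With slide as a block it held 0 (2659 at an unadjusted p under 0.05), and all 5 had the same direction on each slide. The count was 0 in 21 of the 24 refits without 1 array (at least 2166 at an unadjusted p under 0.05), 4 without upstream day 15 replicate 20, 2 without downstream day 3 replicate 17 and 1 without downstream day 15 replicate 27. E-00747 passed in none of these refits, with adjusted p from 0.0506 to 0.136.

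**Figure D2:**
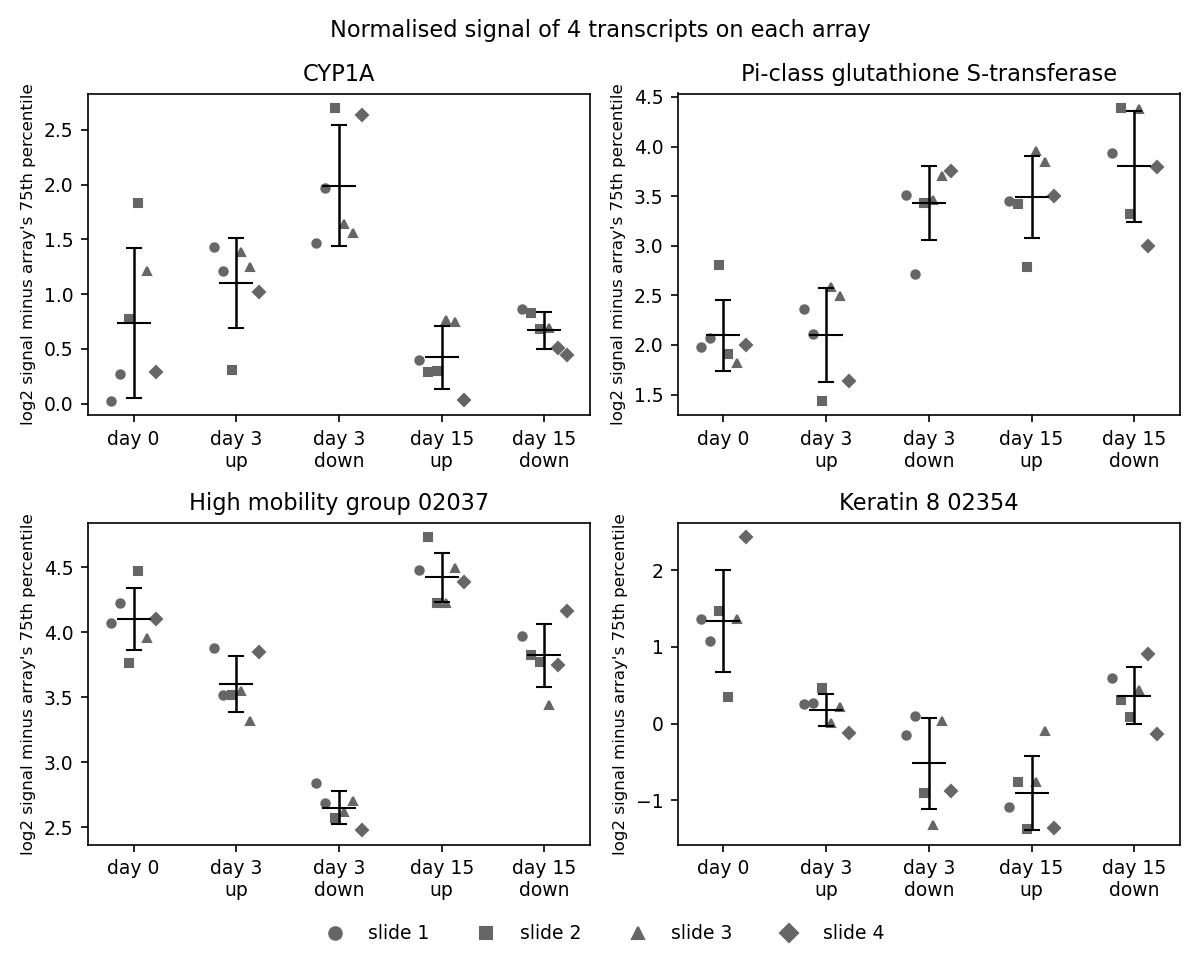
Log2 signal relative to the 75th percentile of the array for CYP1A, the Pi-class glutathione S-transferase, the high mobility group transcript E-02037 and keratin 8 on each of 30 arrays, marked by slide, with the mean and SD of each group of 6. The transferase has means of 2.10 at day 0 and upstream at day 3 against 3.43 downstream at day 3, and E-02037 has 3.60 and 2.65 upstream and downstream at day 3.

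Comparisons of days showed what changed during caging at each site. Arrays of the groups stood in nearly the same order on every slide, so position on the slide went with group. With slide and position in the limma fit the counts of probes past the threshold were 0 upstream and 8 downstream at day 3 against day 0, 0 at either site at day 15 against day 0, and 24 upstream and 201 downstream at day 15 against day 3. Where the count was 0, from 1794 to 3195 probes had an unadjusted p under 0.05. The position slope itself passed for 0 of 26405 probes in limma, with 1025 at an unadjusted p under 0.05. Since position nearly follows group, this fit separates them poorly, and a call lost in it does not show an effect of position. The day 0 arrays are shared by 4 comparisons, whose overlap was therefore not counted. Of the named transcripts that passed, all had the 6 arrays of the later group on the same side of the earlier mean, except 1 of 19 upstream and 2 of 19 downstream at day 15 against day 3, which had 5. The size of a change is uncertain where a group was well above background on at most 3 of 6 arrays. Against day 0 this holds for E-01674, glutamine synthetase and E-00584 downstream at day 3, glutamine synthetase, E-02241 and interleukin 8 upstream at day 15, and E-02241, junB and E-00299 downstream at day 15. Between day 3 and day 15 it holds for the light chain, E-03889 and caspase 3b upstream, for the heavy chain, fish-egg lectin, mucin 19 and E-01606 downstream, and for every transcript with a fold written as at least.

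Upstream day 3 against day 0 showed a rise of protein-folding enzymes of the endoplasmic reticulum. Among 6 transcripts of the unfolded protein response 4 rose. They include the protein disulfide isomerases E-03800, 2.84-fold higher (SE 0.31 in log2, adjusted p = 0.0133), and E-03801 (log2 1.45 ± 0.31, adjusted p = 0.014). The list's median was 1.07, and 5 passed adjusted over the list alone (adjusted p = 3.75e-05, and adjusted p = 0.208 with an estimated correlation). An aldehyde dehydrogenase (E-00213) rose by log2 1.53 ± 0.32 and a cystathionine beta transcript (E-01098), of sulfur amino acid metabolism, by log2 1.07 ± 0.24. Tumor protein p53 (log2 -1.02 ± 0.22, adjusted p = 0.0163, but 0.23 on slide 2) and a heat shock protein (E-01975, log2 -0.96 ± 0.21, adjusted p = 0.0161) fell. So did an ADP-ribosylation transcript (E-00177, log2 -1.13 ± 0.23) and a ubiquitin-conjugating transcript (E-05015, log2 -0.83 ± 0.17).

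As groups at day 3 upstream, proteasome transcripts lay lower (median -0.36, adjusted p = 1.51e-07, and adjusted p = 0.398 with an estimated correlation) and phase II enzymes higher (median 0.42, adjusted p = 0.0118, and adjusted p = 0.417 with an estimated correlation). None of the 41 and 25 transcripts passed, 14 and 6 had an unadjusted p under 0.05, and 0 and 3 passed adjusted over the list alone. Amino acid catabolism had 1 of 9 transcripts that rose, 1 adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.398 with an estimated correlation). Oxidative phosphorylation lay higher (median 0.10) and cholesterol synthesis lower (median -0.75), at adjusted p of 0.0325 and 0.0405, against adjusted p = 0.728 and 0.398 with an estimated correlation. Adjusted over the list alone 0 and 1 of their transcripts passed, and 7 and 1 had an unadjusted p under 0.05. Of lists added after the array's names were seen, mitochondrial ribosomal proteins and histones lay higher and the cytosolic chaperonin lower. Their adjusted p was 0.0181, 0.0411 and 0.0325, against adjusted p = 0.669, 0.438 and 0.208 with an estimated correlation. The cell-type medians were -0.75 for erythrocyte, -0.54 for lymphocyte and -0.42 for bile duct lists, at adjusted p of 0.137, 0.17 and 0.125.

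Limma called 425 probes upstream between day 3 and day 0, 224 higher and 201 lower. With slide as a block 526 passed, 381 of the 425 among them, and at least 94.1% had the same direction per slide. Of the 9 called lists 2, the unfolded protein response and the proteasome, had the same direction on all 4 slides, 5 on 3 slides, and oxidative phosphorylation and mitochondrial ribosomal proteins on 2. The count was 43 when only these 12 arrays were fitted and 1111 with array weights. Without single arrays it ran from 156 to 563, with 188, 271 and 276 without day 0 replicates 1, 2 and 5, and 236, 223, 156 and 271 without upstream replicates 8, 10, 11 and 12. In the fit of 12 arrays only E-00213 of the named transcripts kept its call (adjusted p = 0.0435, the others from 0.0712 to 0.15). Without the dim arrays E-01098 (0.0756) and E-01975 (0.106) lost theirs, and E-01098 also without upstream replicate 11 (0.0567).

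Downstream day 3 against day 0 held conjugation enzymes and CYP1A among the rises. CYP1A rose 2.39-fold (log2 1.26 ± 0.26, adjusted p = 0.0019) and CYP1A9 2.64-fold (log2 1.40 ± 0.37, adjusted p = 0.0128, but -0.15 on slide 3). Of 25 phase II transcripts 11 rose and none fell. Among them were sulfotransferases E-04503 (log2 1.46 ± 0.20, adjusted p = 5.22e-05) and E-04500 (log2 1.47 ± 0.29) and a glutathione S-transferase (E-01816, log2 1.84 ± 0.50). The median was 0.74 and 13 passed adjusted over the list alone (adjusted p = 1.95e-08, and adjusted p = 0.0865 with an estimated correlation). In the unfolded protein response list 5 of 6 rose, with protein disulfide isomerase E-03800 at log2 1.80 ± 0.31 and calreticulin at log2 1.43 ± 0.28. In that list 5 passed adjusted over the list alone (adjusted p = 6.75e-05, and adjusted p = 0.164 with an estimated correlation). An immediate-early transcription factor of the fos family (E-05191) rose 25.1-fold (log2 4.65 ± 0.93, adjusted p = 0.00143). A fumarylacetoacetate transcript (E-01674) rose by log2 2.98 ± 0.50, somatic cytochrome c (E-01186) by log2 1.52 ± 0.29 (-0.03 on slide 4) and estrogen receptor beta by log2 0.88 ± 0.25.

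Among the falls downstream at day 3, glutamine synthetase (E-01789) was lower than at day 0 (log2 -4.36 ± 0.94, adjusted p = 0.00266). It was well above background on 1 array against 6, so the size of its fall is uncertain. Keratins 8 (log2 -1.86 ± 0.28, adjusted p = 0.000115) and 18 (E-02351, log2 -1.67 ± 0.32), hemoglobin alpha (log2 -1.80 ± 0.46) and p53 (log2 -1.52 ± 0.22) fell. Further falls were E-03371 (log2 -2.15 ± 0.28) and a cAMP-responsive transcript (E-00584, log2 -2.49 ± 0.43). An interferon-induced transcript (E-02238), well above background on 0 arrays against 4, was at least 1.75-fold lower (adjusted p = 0.0055). Of 41 proteasome transcripts 12 fell, among them psmd1 (log2 -1.03 ± 0.18, adjusted p = 0.000562). The list's median was -0.46, and 21 passed adjusted over the list alone (adjusted p = 3.82e-11, and adjusted p = 0.164 with an estimated correlation). Cholesterol synthesis had 2 of 4 that fell, 3 adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.273 with an estimated correlation). The cytosolic chaperonin, a list added after the array's names were seen, had 2 of 3 (adjusted p = 0.0189, and adjusted p = 0.0865 with an estimated correlation). The erythrocyte list had 2 transcripts that fell, both hemoglobins, and 1 that rose of 6, with a median of -1.01. The name of the 1 that rose begins with cellular repress (E-00749), which does not tie it to erythrocytes. In the bile duct list 2 of 9 fell. The erythrocyte and bile duct lists had adjusted p of 0.209 and 0.14 in camera.

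Limma called 3402 probes downstream between day 3 and day 0, 1810 higher and 1592 lower (2062 and 1196 with median scaling). A fit with slide as a block called 3699, with 3209 shared and at least 94.5% in the same direction per slide. Without day 0 replicate 6 estrogen receptor beta lost its call (log2 0.64, adjusted p = 0.0541), as it did when only these 12 arrays were fitted (0.0721) or with the mucin covariate (0.0604), and glutamine synthetase stood at -3.59. The latter stood at -4.95 without downstream replicate 16, and fos at 4.06 without downstream replicate 15.

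Upstream day 15 against day 0 showed lower transcripts of the proteasome, of the secretory pathway and of mitochondria. Of 41 proteasome transcripts 23 fell and none rose, among them psmd1 (log2 -1.37 ± 0.18, adjusted p = 1.28e-05) and E-03722 (log2 -1.35 ± 0.20). The median was -0.57, and 27 passed adjusted over the list alone (adjusted p = 8.24e-11, and adjusted p = 0.502 with an estimated correlation). Of 25 translocon and glycosylation transcripts 12 fell, with a dolichyl-phosphate transcript (E-01336) at log2 -1.55 ± 0.28 and ribophorin I at log2 -1.51 ± 0.34. Mitochondrial ribosomal proteins had 11 of 44 that fell (E-02814, log2 -1.45 ± 0.29) and tRNA synthetases 5 of 8 (tryptophanyl, E-04925, log2 -1.71 ± 0.32). Spliceosome transcripts had 3 that fell and 1 that rose of 16. These 4 lists were added after the array's names were seen. They had adjusted p of 3.23e-06, 8.84e-06, 0.00325 and 0.0181, against adjusted p = 0.502, 0.533, 0.502 and 0.555 with an estimated correlation. Of 96 oxidative phosphorylation transcripts 22 fell and 3 rose, cytochrome c (E-01144) by log2 -2.17 ± 0.40, and 25 passed adjusted over the list alone (adjusted p = 0.00398, and adjusted p = 0.617 with an estimated correlation). Cholesterol synthesis had 3 of 4 that fell, with phosphomevalonate kinase at log2 -1.92 ± 0.37, and 3 passed adjusted over the list alone (adjusted p = 0.0333, and adjusted p = 0.533 with an estimated correlation).

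The largest named falls upstream at day 15 were in E-00069, named as an acetyl-coenzyme transcript (11.5-fold, log2 -3.53 ± 0.53, adjusted p = 4.27e-05), and glutamine synthetase (log2 -3.37 ± 0.94, adjusted p = 0.0101). The latter was well above background on 2 arrays against 6, which leaves the size of its fall uncertain. Keratin 8 (log2 -2.25 ± 0.28), the coenzyme Q10 homolog (log2 -2.23 ± 0.36), a heat shock protein (E-01978, log2 -2.24 ± 0.40) and a phosphoglycerate transcript (E-03445, log2 -2.18 ± 0.31) fell too. Among the rises, a cytokine-inducible transcript (E-01188) was higher (log2 3.74 ± 0.88, adjusted p = 0.00276), although not on slide 1 (-1.84, against 3.57 to 6.05 on the others), and interleukin 8 (log2 2.21 ± 0.55) was well above background on 5 arrays against 1. In the interferon and antigen presentation list 5 of 28 rose (E-02241, log2 2.03 ± 0.53), and 3 passed adjusted over the list alone. Its median was 0.63 (adjusted p = 0.0181, and adjusted p = 0.617 with an estimated correlation). Of 6 fish virus-induced TRIM transcripts, a list added after the names were seen, 4 rose, E-01631 2.84-fold (SE 0.31 in log2) and E-05195 by log2 2.19 ± 0.57 (adjusted p = 0.0423, and adjusted p = 0.533 with an estimated correlation). Glutathione S-transferases E-01821 (log2 1.43 ± 0.24) and Pi-class (log2 1.39 ± 0.25), superoxide dismutase (E-04506, log2 1.11 ± 0.19) and catalase (log2 1.17 ± 0.36) rose.

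Ribosomal proteins lay higher upstream at day 15, with 2 that rose and 1 that fell of 84 and a median of 0.27. Adjusted over the list alone 1 passed (adjusted p = 0.00783, and adjusted p = 0.676 with an estimated correlation). In the erythrocyte list 4 of 6 fell (median -1.18) and in the macrophage list 3 of 12 rose (median 0.74), at adjusted p of 0.257 and 0.123. Limma called 6441 probes, 2983 higher and 3458 lower (2174 and 3917 with median scaling). A fit with slide as a block called 7261, with 6279 shared and at least 96.1% in the same direction per slide. Without day 0 replicate 6 catalase lost its call (0.0522) and glutamine synthetase stood at -2.60. E-01188 stood at 4.38 without day 0 replicate 1 and 4.46 without upstream replicate 19, and E-01631 turned to -0.41 with slide and position in the fit.

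Downstream day 15 against day 0 showed falls of proteasome and mitochondrial transcripts. Of 41 proteasome transcripts 21 fell and 1 rose, with psmd1 at log2 -1.80 ± 0.18 (adjusted p = 5.22e-07) and a 26S transcript (E-00017) at log2 -1.43 ± 0.36. Adjusted over the list alone 25 passed (adjusted p = 1.82e-08, and adjusted p = 0.362 with an estimated correlation). Of 96 oxidative phosphorylation transcripts 31 fell and 2 rose, with a cytochrome c oxidase transcript (E-01174) at log2 -2.50 ± 0.40 and cytochrome c at log2 -1.75 ± 0.40. In this list 34 passed adjusted over the list alone (adjusted p = 6.24e-07, and adjusted p = 0.4 with an estimated correlation). Of lists added after the array's names were seen, mitochondrial ribosomal proteins had 13 of 44 that fell (E-02785, log2 -1.13 ± 0.27), translocon and glycosylation 8 of 25 (a signal recognition transcript, E-04303, log2 -1.43 ± 0.19) and tRNA synthetases 4 of 8 (E-04925, log2 -1.74 ± 0.32). Their adjusted p was 4.89e-06, 0.000259 and 0.00499, against adjusted p = 0.4, 0.4 and 0.362 with an estimated correlation. Spliceosome transcripts, with 5 of 16 that fell, and ubiquitin conjugation, with 5 that fell and 1 that rose of 27, were added likewise. They had adjusted p of 0.00248 and 0.00405, against adjusted p = 0.371 and 0.362 with an estimated correlation. Phosphomevalonate kinase (log2 -1.46 ± 0.37), E-03445 (log2 -1.86 ± 0.31) and keratin 8 (log2 -0.98 ± 0.28) fell.

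Phase II enzymes rose downstream at day 15, 10 of 25 with none that fell. Among them were a glutathione S-transferase (E-01812, log2 1.82 ± 0.25, adjusted p = 2.27e-05) and the Pi-class transferase (log2 1.70 ± 0.25, adjusted p = 4.86e-05). The median was 0.92, and 10 passed adjusted over the list alone (adjusted p = 5.58e-05, and adjusted p = 0.362 with an estimated correlation). In the interferon and antigen presentation list 6 of 28 rose (E-02241, log2 2.15 ± 0.53) and 8 passed adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.439 with an estimated correlation). The lymphocyte and macrophage lists had medians of 0.89 and 0.43 beside it and were not called (adjusted p = 0.0907 and 0.322). None of their 9 and 12 transcripts passed in limma, and 2 and 1 had an unadjusted p under 0.05. The TRIM list, added after the names were seen, had 4 of 6 that rose (E-05195, log2 2.55 ± 0.57), with adjusted p = 0.0165, and adjusted p = 0.362 with an estimated correlation. The transcription factors fos (E-05191, log2 3.29 ± 0.93) and junB (log2 2.52 ± 0.63), an anterior gradient transcript (E-00299, log2 2.57 ± 0.42), catalase (log2 1.28 ± 0.36) and superoxide dismutase (log2 1.08 ± 0.19) rose. Limma called 5819 probes, 2535 higher and 3284 lower (1518 and 4727 with median scaling). Phosphomevalonate kinase lost its call when only these 12 arrays were fitted (0.0576). A fit with slide as a block called 6656, with 5672 shared and at least 95.2% in the same direction per slide.

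Upstream day 15 against day 3 compared the longer with the shorter stay at the upstream site. Among the rises were transcripts of immune defence, with a suppressor of cytokine signalling (E-04511), at least 2.50-fold higher (adjusted p = 0.00176), and CD83 (log2 2.79 ± 0.42, adjusted p = 5.19e-05). In the interferon and antigen presentation list 10 of 28 rose, among them a radical SAM transcript (E-03889, log2 1.71 ± 0.44) and MHC class II (E-02697, log2 1.49 ± 0.43). Its median was 0.92, and 12 passed adjusted over the list alone (adjusted p = 0.000222, and adjusted p = 0.506 with an estimated correlation). The TRIM list, added after the names were seen, had 3 of 6 that rose (E-01631, log2 1.41 ± 0.31), with adjusted p = 0.0343, and adjusted p = 0.506 with an estimated correlation. Markers of macrophages (4 of 12, lysozyme log2 2.58 ± 0.65) and of lymphocytes (4 of 9, immunoglobulin light chain E-02199 log2 2.33 ± 0.70) rose beside them. These cell-type lists had adjusted p of 0.0112 and 0.0338, against adjusted p = 0.536 and 0.536 with an estimated correlation, and 4 and 7 passed adjusted over the list alone. Glutathione S-transferases Pi-class (log2 1.39 ± 0.25) and E-01821 (log2 1.38 ± 0.24) rose as well. Without upstream day 15 replicate 23 the light chain stood at 1.66, on slide 1 it was -0.63, and its call ended when only these 12 arrays were fitted (0.0706).

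Transcripts of protein production and mitochondria fell upstream between day 3 and day 15. Mitochondrial ribosomal proteins had 23 of 44 that fell, translocon and glycosylation 16 of 25 (ribophorin I, log2 -1.94 ± 0.34), tRNA synthetases 5 of 8, the spliceosome 6 of 16 and ubiquitin conjugation 9 of 27. These 5 lists were added after the names were seen. They had adjusted p of 6.03e-10, 6.73e-08, 0.00092, 0.0043 and 0.0338, against adjusted p = 0.392, 0.392, 0.392, 0.506 and 0.413 with an estimated correlation. Of 96 oxidative phosphorylation transcripts 30 fell and none rose, with cytochrome c at log2 -2.54 ± 0.40 and its somatic form (E-01186) at log2 -2.31 ± 0.29. In this list 35 passed adjusted over the list alone (adjusted p = 4.66e-06, and adjusted p = 0.536 with an estimated correlation). The unfolded protein response list had 5 of 6 that fell (E-03801, log2 -1.58 ± 0.31, and calreticulin, log2 -1.40 ± 0.28), 5 adjusted over the list alone (adjusted p = 0.0013, and adjusted p = 0.413 with an estimated correlation). The proteasome had 8 that fell and 1 that rose of 41, 9 adjusted over the list alone (adjusted p = 0.00129, and adjusted p = 0.596 with an estimated correlation). Gluconeogenesis and glycolysis had 5 of 14 that fell, 5 adjusted over the list alone (adjusted p = 0.0343, and adjusted p = 0.536 with an estimated correlation). Ribosomal proteins lay higher as a group (median 0.25, adjusted p = 0.0338, and adjusted p = 0.963 with an estimated correlation), although the 2 that passed fell, and 1 passed adjusted over the list alone. Caspase 3b (log2 -3.01 ± 0.64), the coenzyme Q10 homolog (log2 -2.69 ± 0.36), keratin 8 (log2 -1.09 ± 0.28) and angiopoietin-like 4 (log2 -1.87 ± 0.34) fell. A transcript whose name begins with programmed cell (E-03672) was at least 4.22-fold lower (adjusted p = 0.000111). Limma called 6875 probes, 3218 higher and 3657 lower (2255 and 4406 with median scaling). A fit with slide as a block called 7692, with 6741 shared and at least 95.7% in the same direction per slide.

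Downstream day 15 against day 3 showed rises of antibody and interferon genes. Immunoglobulin light chain (E-02199) was at least 5.60-fold higher (adjusted p = 0.000797) and heavy chain (E-02196) rose by log2 2.47 ± 0.62. Of 9 lymphocyte markers 7 rose, 7 adjusted over the list alone (median 1.42, adjusted p = 0.00172, and adjusted p = 0.344 with an estimated correlation). Of 28 interferon and antigen presentation transcripts 13 rose, among them E-03889 (log2 1.86 ± 0.44), MHC class II (E-02701, log2 1.85 ± 0.48) and E-02238, at least 1.97-fold higher (adjusted p = 0.00234). Their median was 1.35, and 19 passed adjusted over the list alone (adjusted p = 5.78e-07, and adjusted p = 0.344 with an estimated correlation). The TRIM list, added after the names were seen, had 5 of 6 that rose (E-05195, log2 2.43 ± 0.57, but -0.43 on slide 3), with adjusted p = 0.0139, and adjusted p = 0.344 with an estimated correlation. Of 12 macrophage markers 4 rose, 4 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.466 with an estimated correlation). Fish-egg lectin (log2 5.34 ± 1.53), mucin 19 (log2 4.13 ± 1.12) and an Fc fragment transcript (E-01606, log2 4.14 ± 1.18) rose, while the mucin score went from -1.58 ± 2.34 to 2.10 ± 3.15 (SD, n = 6) between these groups. The lectin was not higher on slide 2 (-0.16). Mucin 19 is itself part of that score, and with the score as a covariate E-01606 lost its call (log2 1.60, adjusted p = 0.0881). Interleukin 8 was at least 1.32-fold higher (adjusted p = 0.00509). The DNA damage and p53 list had 2 of 10 that rose, p53 by log2 1.25 ± 0.22 and a growth arrest transcript (E-01888) by log2 2.21 ± 0.53, and 4 passed adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.288 with an estimated correlation). The bile duct epithelium list had 2 of 9 that rose, 5 adjusted over the list alone (adjusted p = 0.0251, and adjusted p = 0.29 with an estimated correlation). Mean scores of the skeletal muscle list and of the fibroblast and stellate list were higher at day 15 too, although neither list was called. Under the mucin covariate the macrophage and bile duct lists were no longer called (medians 0.52 and 0.64, adjusted p = 0.304 and 0.0924), and the lymphocyte list was (1.25, adjusted p = 0.0179). Without the covariate the macrophage median was 1.07 and the bile duct median 0.573, so the bile duct median did not shrink. Peroxiredoxin 1 rose by log2 1.49 ± 0.30. Without downstream day 15 replicate 26 the lectin, mucin 19 and E-01606 stood at 6.47, 4.87 and 5.23. The lectin stood at 5.95 without downstream day 3 replicate 14 and mucin 19 at 3.52 without downstream day 15 replicate 28.

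Mitochondrial transcripts fell downstream between day 3 and day 15. Of 96 oxidative phosphorylation transcripts 34 fell and none rose, with somatic cytochrome c (E-01186) at log2 -2.33 ± 0.29, cytochrome c at log2 -2.20 ± 0.40 and cytochrome c oxidase (E-01174) at log2 -1.70 ± 0.40. In this list 39 passed adjusted over the list alone (adjusted p = 5.97e-10, and adjusted p = 0.344 with an estimated correlation). Of lists added after the names were seen, mitochondrial ribosomal proteins had 14 of 44 that fell, translocon and glycosylation 3 of 25, the spliceosome 5 of 16 and ubiquitin conjugation 6 that fell and 1 that rose of 27. Their adjusted p was 4.3e-06, 0.00906, 0.0134 and 0.0268, against adjusted p = 0.376, 0.501, 0.382 and 0.344 with an estimated correlation. The unfolded protein response list had 4 of 6 that fell (calreticulin, log2 -1.39 ± 0.28), 4 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.382 with an estimated correlation). Cysteine dioxygenase (log2 -2.31 ± 0.41) and a sulfotransferase (E-04500, log2 -1.06 ± 0.29, with its call lost under the mucin covariate, 0.054) fell. Limma called 5652 probes, 2667 higher and 2985 lower. The balance moved to 5307 lower of 6946 with median scaling and to 1974 higher and 3364 lower with quantile scaling. With slide as a block 6173 passed, with 5409 shared and at least 95.5% in the same direction per slide. The comparisons of day 15 with day 3 at the 2 sites share no array. Between them 1252 probes were higher at both sites (325 expected if independent), 1913 lower at both (413.4 expected) and 6 opposite (733.2 expected). Several probes can stand for 1 transcript, and at both sites the day 15 arrays lay mostly at later slide positions. The expected counts allow for neither, so the overlap does not tell time from position.

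**Figure D3:**
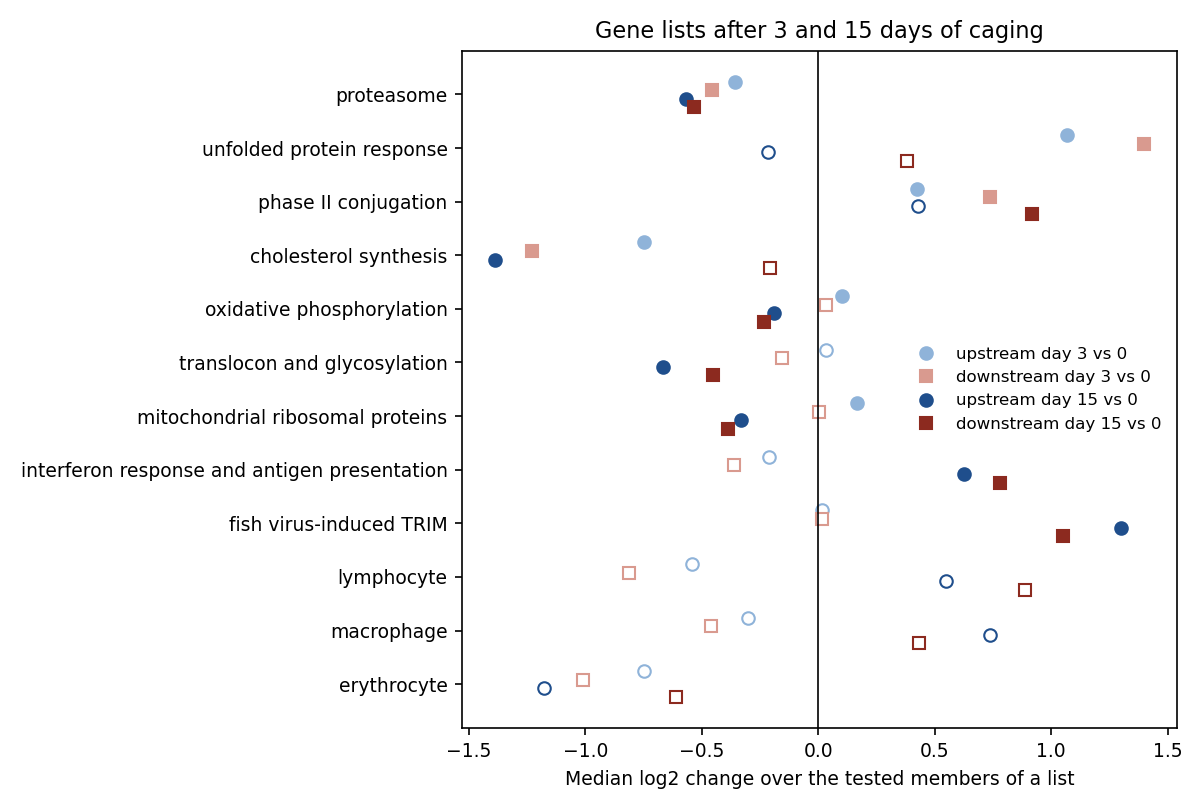
Median log2 change of the transcripts of selected gene lists at day 3 and at day 15, each against day 0, at both sites. Markers are filled where limma's camera test with a preset correlation gave an adjusted p under 0.05. Day 15 against day 3 is not drawn. There oxidative phosphorylation has medians of -0.27 upstream and -0.37 downstream, and the interferon and antigen presentation list 0.92 and 1.35.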

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

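Of the tests in this part, the comparison of lymphocyte with erythrocyte markers and the count of slides and probes for E-02037 were chosen after the result was seen. In 263 combinations of group and value an array far from the other 5 was sought, by its gap to the nearest array as a share of the group's range, and 19 were found where chance gives 13.2 (1 in 20).

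At day 0, replicate 6 was highest for glutamine synthetase (0.709), replicate 3 for the Pi-class transferase (0.749) and replicate 2 for E-01812 (0.657), and replicate 4 was lowest for E-00584 (0.635) and keratin 18 (0.664). Upstream at day 3, replicate 9 was lowest for CYP1A (0.634) and CYP1A9 (0.733), replicate 7 for E-01186 (0.658), replicate 8 for E-00930 (0.640) and replicate 12 for E-01726 (0.851), and replicate 10 was highest for caspase 3b (0.697). Downstream at day 3, replicate 14 was lowest for the Pi-class transferase (0.685), and replicates 16 and 18 were highest for E-01727 (0.658) and metallothionein E-02654 (0.664). Upstream at day 15, replicates 19, 21 and 23 were lowest for E-01188 (0.636), E-02814 (0.647) and E-00069 (0.629). Downstream at day 15, replicate 26 was lowest for E-04925 (0.722) and E-00017 (0.627).

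The site difference changed between day 3 and day 15 for 5 probes, among them E-00747 (log2 -0.745), and for 6 gene lists, although these calls were fragile. With slide as a block limma called 0 probes (2659 at an unadjusted p under 0.05), E-00747 passed in none of 24 refits without 1 array, and none of the 6 lists passed with an estimated correlation. In control spots outside the comparisons, those whose names begin with ETG, a median of 8.33% per array was well above background (1.28% to 12.2%), and on 28 of 30 arrays this exceeded the share of negative control spots, which reached 3.90% at most.

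For each comparison 100 splits of its arrays were counted, the real one included. Only the real split reached its count for the sites at day 3 (24 probes, highest other 7), upstream at day 3 and at day 15 against day 0 (425 and 6441, highest other 3 and 696), downstream at day 3 and at day 15 against day 0 (3402 and 5819, highest other 35 and 2380), and day 15 against day 3 upstream and downstream (6875 and 5652, highest other 3708 and 1874). For the sites at day 15 (74, highest other 196) and the interaction (5, highest other 328), 2 of 100 splits were as large. In these fits, which leave out slide, the share was under 0.05 for all 9, without correction over the 9 comparisons. For the interaction that carries little, since the fit with slide as a block ended its 5 calls. It carries little for the sites at day 15 too, since their calls ended when only the arrays compared were fitted. Chance is thus not excluded for these 2. In each of these 2 comparisons a single other split called more probes than the real one, and what set that split apart was not tested.

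Between day 15 and day 3, 6875 probes differed upstream and 5652 downstream, against at most 74 between the sites. If position on the slide were the source, arrays at like positions would differ little. But between 4 upstream day 15 and 5 downstream day 3 arrays at positions 4 to 6, which also differ in site, 3421 probes passed. Signal over background gave a median share of 0.00239 (SE 0.0244) of the change of the called probes. A lower share of hepatocytes, with nothing else changed, would raise other cell types alike. Yet the lymphocyte list differed by 1.14 upstream and 1.59 downstream and the erythrocyte list by -0.12 and 0.47. The one-sided exact permutation p was 8.32e-05 over both sites and 0.00649 at each, of 924 relabellings. The erythrocyte list also holds E-00749, which its name does not tie to erythrocytes. These values argue against position and signal over background, and the lymphocyte and erythrocyte lists did not rise evenly. Downstream the macrophage and bile duct lists rose too (medians 1.07 and 0.573), as did the mean muscle and fibroblast scores. There the erythrocyte list, 1 of the pair chosen afterwards, rose least in mean score. A lower share of hepatocytes is thus not excluded downstream. An uneven change of cell types, such as more lymphocytes, would also give unequal lists, so the comparison of these lists cannot decide on it. Time in the cage may be the source, although any other change between the days stays open and untested.

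Between the sites, the Pi-class transferase was higher at day 3 and E-02037 lower at both times. Without the dim day 3 arrays the transferase differed by 1.54 (6 against 4 arrays), against 1.33 on all arrays. The dim arrays, upstream replicates 10 and 11, had the highest upstream levels (2.581 and 2.497), so leaving them out could only raise the difference. Low levels on them thus did not give it. At positions 3 and 4 the transferase differed by 1.45 (3 downstream against 4 upstream arrays), which argues against position as the source. All downstream arrays already lay above all upstream arrays at day 3 (lowest 2.712, highest 2.581), so separation at these positions adds nothing. E-02037 was lower on 4 of 4 slides and with 6 of its 6 probes, so its difference was not confined to 1 probe or 1 slide. At each time all its downstream arrays lay below all upstream arrays. The count of slides follows from that and is not separate support. The slope on position gave a share of 0.0749 (SE 0.136) of its site difference, more than 2 SE below the 0.5 that position as the cause would need. It was not 2 SE below 0.25, the bound first set for excluding position, so a smaller part stays open, and the reading against 0.5 was chosen after the value was seen. With slide and position in the fit it differed by -0.983 at day 3 (adjusted p = 0.0327) and by -0.657 at day 15, where the call ended (0.178). The site is the explanation the design names, and it may account for both, as a hypothesis that rests for the transferase on a fragile call. It ended without any of 6 single arrays, with slide and position in the fit (1.47, adjusted p = 0.284) and when only the 12 arrays compared were fitted (1.33, adjusted p = 0.152).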

How the results depend on the processing

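The alternatives that leave out the 4 dimmest arrays, use the mucin score, keep identical sequences apart, leave targets unjoined, drop hand-matched names, use only the earlier lists or scale the lists by the median were chosen after the result was seen, and the others before the data were examined. Signal over background limits the tests, since probes dim in every group were not tested and 16261 probes were well above background on all 30 arrays. For results that moved, the cause was not tested unless named. In comparisons of day 15 with an earlier day, counts stayed within 1.5 times under every alternative except the minimum log2 change and slide with position. The sign of 0 of 83 list medians turned under median, quantile or normexp scaling, while the direction of the list test turned for 1 under quantile scaling.

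The minimum log2 change of 1, which by construction keeps fewer probes, gave 9, 28, 2, 205, 2790, 1436, 2214, 2839 and 2448 probes in the order sites at day 3 and day 15, interaction, upstream at day 3 and day 15 against day 0, downstream at day 3 and day 15 against day 0, and day 15 against day 3 upstream and downstream; the unrestricted counts are 24, 74, 5, 425, 6441, 3402, 5819, 6875 and 5652. Slide with position gave in that order 8, 9, 0, 0, 0, 8, 0, 24 and 201, with 1640, 2784, 2551, 3195, 2451, 3022, 1794, 4011 and 4081 at an unadjusted p under 0.05. Slide as a block gave 44 for the sites at day 3 and 0 for the interaction. Only the groups compared, with fewer arrays for the spread, gave 4, 0, 0 and 43 for the first 4. Without a filter, with more probes to adjust for, the first 4 were 13, 36, 0 and 141, and with the filter on all 30 arrays 45 for the sites at day 3 and 8 for the interaction. Array weights gave 90 for the sites at day 3, 0 for the interaction and 1111 upstream at day 3. The day 15 site count was 138 with median scaling, 139 with quantile scaling and 139 with the deposited value table, and the interaction 3 with median scaling and 1 with identical sequences apart. Without the 4 dimmest arrays the sites at day 15 had 17 (16 of the 74 among them), the interaction 0 and upstream at day 3 205. The mucin covariate gave 41, 0 and 262 for these. The interaction's counts of 0 stood beside 2013 to 3137 probes at an unadjusted p under 0.05, and that of the sites at day 15 beside 3062.

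Median scaling put the median change of all probes at -0.18 downstream at day 15 against day 3 and at -0.11 in the interaction, where scaling by the 75th percentile gave 0.03 and -0.01. It changed the balance of higher and lower probes to 13 and 16 for the sites at day 3, 21 and 117 at day 15, 0 and 3 for the interaction, 2174 and 3917 upstream at day 15 and 2062 and 1196 downstream at day 3 against day 0, 1518 and 4727 downstream at day 15 against day 0, and 2255 and 4406 upstream at day 15 against day 3. Downstream at day 15 against day 3 it called 6946 probes, of which 5307 were lower. Downstream at day 15 against day 3 quantile scaling gave 1974 and 3364 and the deposited values 1960 and 3350, and normexp gave 12 and 15 for the sites at day 3 and 21 and 74 at day 15.

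Leaving out 1 array gave 11 to 27 and 42 to 97 for the sites at day 3 and day 15, 0 to 4 for the interaction, 156 to 563 upstream at day 3, 4721 to 6576 upstream at day 15, 2729 to 3467 downstream at day 3 and 4364 to 6501 downstream at day 15 against day 0, and 5431 to 7660 upstream and 4289 to 6235 downstream at day 15 against day 3. Of 83 list calls 0 held with an estimated correlation, 50 lists were called without hand-matched names and 53 with only the earlier lists, and 81 of the 83 were kept with slide as a block, 74 with the mean over probes, 72 with quantile scaling, 79 with normexp, 54 with fry and 68 without the dim arrays or with the mucin covariate. In the order given above, 5 of 6, 6 of 11, 4 of 6, 2 of 9, 7 of 10, 5 of 5, 8 of 10, 11 of 14 and 11 of 12 called lists had the same direction on all 4 slides. Fry itself called in that order 1, 2, 3, 4, 18, 10, 19, 16 and 18 of 40 lists, so the calls it kept lie mostly in the comparisons of days. The list whose test turned under quantile scaling was that of ribosomal proteins in the interaction (adjusted p = 0.768), and its median stayed negative at -0.0254.

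With slide and position, genes of the naming rule that had passed turned in 12 of 127 upstream and 15 of 112 downstream at day 15 against day 0, and in 1 of 117 upstream and 2 of 121 downstream at day 15 against day 3. Of the transcripts given in the report, those that turned were not past the threshold, apart from TRIM E-01631 upstream at day 15 against day 0 (-0.406 with slide and position). For the sites at day 3 these were metallothionein E-02654 (-0.00526 without upstream replicate 11, -0.114 without downstream replicate 18 and up to 0.41 without others, -0.225 without the dim arrays), metallothionein 1 (0.00221) and estradiol receptor alpha (0.00136) with array weights, and CYP3A E-01183 (-0.00124 without the dim arrays) and E-01182 (-0.0105 without upstream replicate 9 and up to 0.566 without others). At day 15 they were CYP1A9 (0.0201 without upstream replicate 20, 0.226 without downstream replicate 28 and down to -0.230 without others, 0.101 with the mucin covariate), metallothionein 1 (0.127 with quantile scaling, 0.135 with the deposited table, 0.0506 without upstream replicate 21 or the dim arrays, 0.0152 and 0.0441 without downstream replicates 25 and 29 and down to -0.204 without others) and heme oxygenase 1 (-0.240 with slide and position, -0.357 with the mucin covariate, -0.0656 without upstream replicate 21 or the dim arrays, -0.122 and -0.00603 without downstream replicates 28 and 29 and up to 0.426 without others).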

Other observations

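Of the tests in this part, those of slide and of signal over background against the mucin score, and the mucin markers themselves, were chosen after the result was seen. Estrogen-related transcripts, 3 in number, changed against day 0: 2 rose upstream and 2 downstream at day 15, with medians of 0.48 and 0.62, and downstream at day 3 2 rose and 1 fell, while the list itself was not called (adjusted p from 0.186 to 0.417). Phase I enzymes other than CYP1A had 2 of 9 that rose at day 15 against day 0 at either site, with medians of 0.42 upstream and 0.91 downstream (adjusted p = 0.426 and 0.186). Of 12 heat shock transcripts, none rose and 3 upstream and 4 downstream fell from day 0 to day 15.

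Fatty acid oxidation and ketogenesis changed in both directions between day 3 and day 15, with 1 of 10 that rose and 3 that fell at each site (medians -0.50 and -0.37, adjusted p = 0.392 and 0.190). Acute phase and complement transcripts, 17 in number, had 2 that rose and 4 that fell upstream and 4 and 2 downstream (adjusted p = 0.821 and 0.784). Translation factors had 10 that fell and 4 that rose of 51 from day 0 to day 15 at each site, beside 334 falls and 226 rises upstream and 338 and 200 downstream among all named transcripts. Cathepsins had 2 upstream and 1 downstream of 9 that rose and none that fell. The lists of translation factors and cathepsins were added after the array names were seen, and none of these lists was called. The hepatocyte list was not called either (adjusted p from 0.173 to 0.989), with at most 1 of 10 past the threshold in any comparison and medians from -0.04 to 0.52, the highest downstream at day 3 against day 0.

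Mucin transcripts differed between arrays of the same group far more than others did. Mucin 2 (E-02867) had the largest within-group SD of 2233 named transcripts (4.47, median 0.403), and the first component of the within-group variance (15.5%) had a correlation of 0.973 in size with a score of 5 mucin transcripts. The score was 1.06 ± 2.41 (SD, n = 6) at day 0, -0.75 ± 2.16 upstream and -1.58 ± 2.34 downstream at day 3, and -0.83 ± 3.31 upstream and 2.10 ± 3.15 downstream at day 15.

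A candidate explanation is RNA of a mucosal epithelium in some liver samples, which would bring other epithelial transcripts along. Of 7 such transcripts 2 had a within-group correlation above 0.5 with the score over 30 arrays, with a median of 0.315: claudin 23 (r = 0.931, rho = 0.909) and occludin (r = 0.751, rho = 0.720), at permutation p of 1e-05 and 8e-05 (adjusted 7e-05 and 0.00028), so the test left it open. Slide explained a share of 0.171 of the score's within-group variance (permutation p = 0.217), and the squared correlation with signal over background was 0.179 (r = 0.423, permutation p = 0.0358), and both leave most of the variance unexplained. Within groups the score also went with the bile duct list (r = 0.878, rho = 0.859, and 0.898 without the 2 arrays farthest from the median) and the skeletal muscle list (r = 0.794, rho = 0.777, and 0.799), each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Beyond these 3 no explanation was tested, and the design names no biological one for a spread within groups. The bile duct and mucin changes given for the cages could in part reflect such differences between samples. With the score as a covariate the median of the bile duct list between the sites at day 15 went from 0.58 to 0.47 and its call ended (adjusted p = 0.0558), while in the interaction the list stayed called (0.42, adjusted p = 0.0343), and the count of probes went from 74 to 41. Keratin 8 lost its call there too (adjusted p = 0.0997), but its difference stayed at 1.27, so the score did not account for it.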
